A study of Mus musculus with 9 samples.

How the data were processed

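Polyadenylated RNA of alveolar macrophages, isolated from mouse lung by fluorescence-activated cell sorting, was measured by bulk RNA sequencing in 9 libraries. The labels place 4 libraries in the wild type group and 5 in the Suz12 conditional knockout group, all on a C57BL/6 background, and the series text calls the libraries of each group biological replicates. Whether each library came from a single mouse or from a pool, the sex of the mice, the sorting gate, the Cre driver and the deleted exons are not given in the sources used here. Libraries were made with the TruSeq RNA kit and sequenced on a NextSeq 500 as single reads of 85 bases, between 19 and 56 M (M, 1e6) per sample, per the series text.

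The authors deposited whole-number counts per gene, with the gene's Entrez identifier and its length in bases, in a table of all 9 libraries and again in 9 tables of single libraries. The counts in all 9 single tables were equal to those in the joint table, so the joint table was used. The counts were made with featureCounts on the mm10 genome build, per the submitters' processing notes. The aligner, the versions, the annotation release and the strand setting are not given in the sources used here. The table held 27179 genes. Symbols and coordinates came from a RefSeq gene table of GRCm38.p6, the assembly that mm10 represents, which named 25275 of the identifiers. The other 1904 were kept under their identifiers. All identifiers entered library sizes and filters.

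The comparison was knockout against wild type over all 9 libraries, with no covariate. Counts were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (robust glmQLFit, TMM scaling, filterByExpr by group), which left 12840 genes, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Each log2 fold change is knockout minus wild type, with the standard error derived from the test statistic. Levels are counts per 1e6 (CPM) of the TMM-scaled library, computed here from the deposited counts, and log2 CPM uses a prior count of 2. A fold change against a group with 0 counts was taken against a floor of 3 counts over that whole group and is a lower bound. Such floors cover counting error only, because no molecular identifiers are given for the reads. Differences in single library measures were tested with two-sided exact permutation tests over the 126 splits of 9 libraries into 4 and 5. Total counts ranged from 13.8 to 45.6 M per library.

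Before the data were examined, 25 gene lists and 12 lists of markers of other cell types were fixed. Of these 37 lists, 30 had at least 5 tested genes and were tested with camera (limma 3.58.1) at its preset correlation between genes of 0.01, with adjustment over the 30 lists. Each list was also tested with the correlation estimated from the data and with fry, whose p-value asks whether the genes of a list move in the same direction on balance and does not compare them with other genes. The named genes were also set by a rule fixed before the data were examined. The rule took Suz12, and the 8 genes with the largest log2 fold change in each direction among those past the threshold with a mean log2 CPM of at least 1 and no overlap between the groups, without predicted gene models. It then took from each gene list called by camera the 3 members with the smallest adjusted p, from each other gene list the member with the smallest adjusted p, and up to 4 members of the PRC2, CDK inhibitor and alveolar macrophage identity lists. The lists of markers of other cell types gave no named genes. A list with no member past the threshold gave its most abundant member. The rule named 54 genes, and any other gene is named only where a count was small or a feature was singled out, after its values were seen. Some genes that the rule or a small count would name are not reported here. The annotated spans of 7 named genes (Ccl6, Col4a2, Gins2, Plekha6, Rbbp4, Wdfy1 and Xist) overlap another counted gene, and without the strand setting reads in the overlap cannot be assigned. Bcl2a1a has near-identical paralogs, so its counts are uncertain.

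Gene length was examined because the fold changes followed it. The correction, chosen after seeing the data, fitted a loess curve (span 0.5) of each library's log2 CPM deviations on log2 gene length and entered it as an offset, and GC content was treated likewise with transcript sequences of GENCODE vM21, which gave a value for 92.3% of tested genes. Each list's median was also set against 10000 random lists of other genes, drawn from the 100 nearest genes in length and mean expression. For missed genes, each library thinned to equal depth was compared with the mean CPM of the other libraries of its own group, a comparison added after seeing the data. The rate of genes missed by a wild type library as deposited was estimated per expression level from genes that the other wild type libraries detected.

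The alternatives planned before the data were examined were DESeq2-style size factors, library size without a composition factor, no filter on low counts, a stricter filter of 50 counts in 4 libraries, DESeq2 1.42.0, limma voom with quality weights, a test against a 1.5-fold minimum change, the number in the sample titles as a block, the Xist level as a covariate, and leaving out each library in turn, and for lists the estimated correlation, fry, camera on the voom fit, and adjustment over the list alone. The alternatives added after seeing the data were the corrections for length, for GC content and for both, only genes of mean log2 CPM of at least 4, only libraries with Xist above or below 16 CPM, and all libraries thinned to the total of the shallowest. The 9 libraries were also split at random into groups of 4 and 5, with 100 splits drawn, the real split included.

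The scripts were tested on simulated data. Counts were drawn for the real genes from their means, dispersions and library sizes, with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. The changed genes were drawn only from those with a mean of at least 4 CPM, and both groups shared each gene's dispersion. Neither the length trend nor the larger share of missed genes in wild type was included. The shares below therefore do not cover genes of low counts and may differ in the real data. For this comparison edgeR recovered 43.3% of genes changed 1.5-fold, 71.6% of those changed 2-fold and 95.5% of those changed 4-fold among 12556 genes, with 5.41% of its calls false. The same shares for DESeq2 were 58.2%, 79.1% and 97.0% with 15.2% false, and for limma 40.3%, 73.1% and 95.5% with 5.44% false. A simulated length trend without any list effect gave 1093 false calls among 12529 genes and a camera adjusted p of 6.64e-30 for oxidative phosphorylation. After the length correction it gave 0 calls and an adjusted p of 0.975. The trend was linear and the same in every knockout library, so its removal is what the method does by construction. No true change in short genes was simulated, so this does not show whether the correction would also remove one. Libraries of the same group were compared for duplicates, and chi-square per degree of freedom was 22.3 or more for each pair, so each counted as 1 replicate. No column of other samples was present, and no sample was left out.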

Results

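Alveolar macrophages, the resident phagocytes of the lung's airspaces, were sorted from the lungs of mice aged 1 week and profiled by RNA sequencing. The libraries came from 4 wild type mice or pools and 5 with a conditional knockout of Suz12, a core subunit of Polycomb repressive complex 2 (PRC2), which places a repressive methyl mark on histone H3. The wild type libraries held 22.5, 24.8, 13.8 and 25.3 M counts assigned to genes (M, 1e6), and the knockout libraries 45.4, 34.8, 38, 18.6 and 45.6 M. The mean total was 21.6 ± 5.34 M (SD, n = 4) in wild type and 36.5 ± 11 M (SD, n = 5) in knockout.

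The comparison asked which transcripts differed between macrophages with and without Suz12. Suz12 itself (Entrez Gene 52615, chromosome 11, positions 79993106 to 80034123 of GRCm38) was lower in every knockout library than in every wild type library. It stood at 67.5, 76.7, 51.7 and 70.7 counts per 1e6 (CPM) in the wild type libraries and at 11.9, 14.7, 21.8, 13.1 and 18.5 CPM in the knockout libraries. The mean fell from 66.6 ± 10.7 CPM (SD, n = 4) to 16 ± 4.11 CPM (SD, n = 5), a log2 fold change of -2.06 (SE 0.18, adjusted p = 1.69e-05, edgeR quasi-likelihood test). Counts were made over the whole gene and the deleted exons are not given in the sources used here, so the remaining counts were not assigned to deleted or retained exons.

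**Figure D1:**
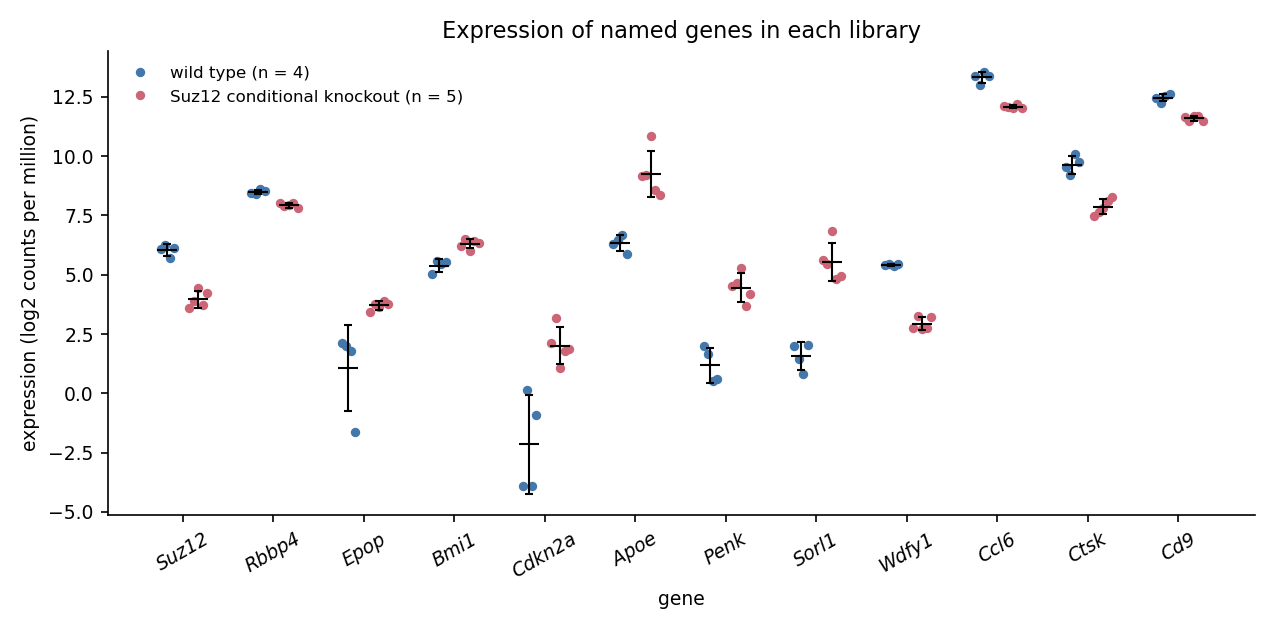
Expression of 12 named genes in each library, in log2 CPM (points), with the mean and SD of each group (black bars) for wild type (blue, n = 4) and Suz12 conditional knockout (red, n = 5). The groups do not overlap for any of the 12 genes, and a value of -3.92 stands for 0 counts.

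The largest increases were in genes that were near silent in wild type macrophages. Sorl1, a sorting receptor of the LDL receptor family, rose from 3.07 ± 1.13 to 53.4 ± 35.8 CPM (log2 fold change 4.09, SE 0.53), and Penk, the precursor of enkephalin peptides, from 2.45 ± 1.24 to 23.5 ± 9.82 CPM (log2 fold change 3.24, SE 0.38). Plcb4, a phospholipase C, gave the largest log2 fold change among genes of mean log2 CPM of at least 1 whose groups did not overlap, 5.16 (SE 0.92), from 0.524 ± 0.864 to 21.0 ± 10.7 CPM. Most wild type Plcb4 came from library 2 (0.90 log2 CPM, the others -3.92 to -1.47). Without that library the log2 fold change was 7.43, and with voom Plcb4 was not called (adjusted p = 0.223). The others were Egln3, an oxygen-sensing prolyl hydroxylase (3.61), Plekha6 (3.56), Col4a2, a basement membrane collagen chain (3.5, SE 0.83, and 2.98 to 4.34 with each library left out in turn), Slc22a4, an organic cation transporter (3.35), and Nr4a3, an orphan nuclear receptor (3.30). Among the largest decreases, Wdfy1, an endosomal phosphoinositide-binding protein, fell from 42.7 ± 1.35 to 7.71 ± 1.47 CPM (log2 fold change -2.47, SE 0.15) and had the smallest adjusted p of all tested genes, 1.46e-06 by edgeR. The short genes of the secreted proteins Wfdc21 (-2.50, and -1.84 after the length correction) and Wfdc17 (-2.17 and -1.52), the chemokine Ccl9 (-2.28), the cholesterol hydroxylase Ch25h (-2.40), the mitochondrial leucyl-tRNA synthetase Lars2 (-2.32), the transcriptional inhibitor Id3 (-2.10) and the nuclear long noncoding RNA Malat1 (-2.08) also fell.

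Across 12840 tested genes, 1152 were higher and 1409 lower in knockout at an adjusted p under 0.05 by edgeR, of which 327 and 149 changed by more than 2-fold. The groups did not overlap for 977 of the higher and 1088 of the lower genes, and for 20.8% of all tested genes against 1.59% by chance. Nr4a3 and Slc22a4 were called by a narrow margin, with adjusted p of 0.0289 and 0.0313. Without knockout library 1, 2, 4 or 5 or wild type library 2 or 4 the adjusted p of Nr4a3 was 0.0502 to 0.0670, and without knockout library 2 or any wild type library that of Slc22a4 was 0.0552 to 0.0745.

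Gene length, library complexity and scaling moved with genotype and bear on these counts. In the shortest 10% of genes (62 to 970 bases) the median log2 fold change was -0.42, with 18 genes higher and 504 lower, and in the longest 10% (6045 to 83437 bases) it was 0.14, with 197 higher and 33 lower. After the length correction 1247 genes were higher and 835 lower, so that 59.9% of called genes were higher, against 45% without it. The correction also moved the median log2 fold change of all tested genes from 0.04 to 0.08, and to 0.125 in the shortest 10%. Of the genes called without the correction, 950 of the higher and 740 of the lower were called in the same direction with it. With libraries scaled by their totals alone, 66% of calls were higher (1966 higher and 1013 lower) and the median log2 fold change of all tested genes was 0.15, against 0.04 with TMM. At an equal depth of 13814799 counts, 12970 ± 394 genes were detected in wild type (SD, n = 4) and 15286 ± 395 in knockout (SD, n = 5; exact permutation p = 0.00794, the smallest that 126 splits allow). Identifiers without a symbol took 3.39 ± 0.73% of counts in wild type and 1 ± 0.13% in knockout (exact permutation p = 0.00794).

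**Figure D2:**
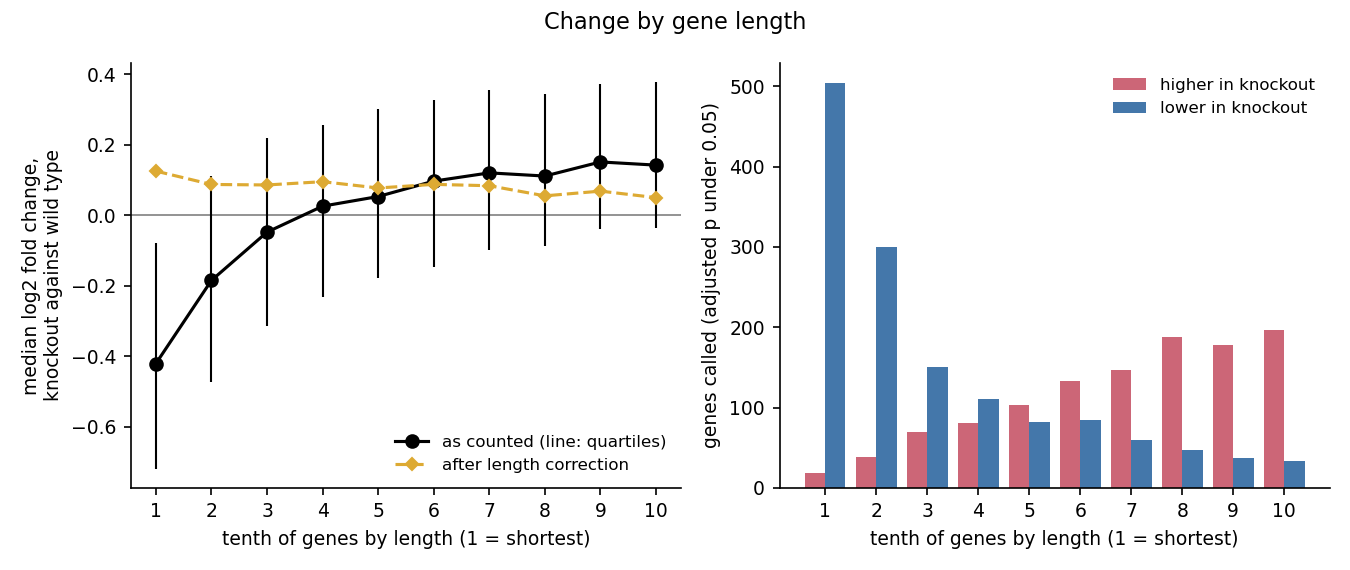
Left, median log2 fold change of knockout against wild type in 10 equal groups of the 12840 tested genes by length, as counted (black, with quartiles) and after the length correction (yellow). Right, number of genes called higher (red) and lower (blue) in each group, from 18 higher and 504 lower in the shortest to 197 higher and 33 lower in the longest.

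**Figure D3:**
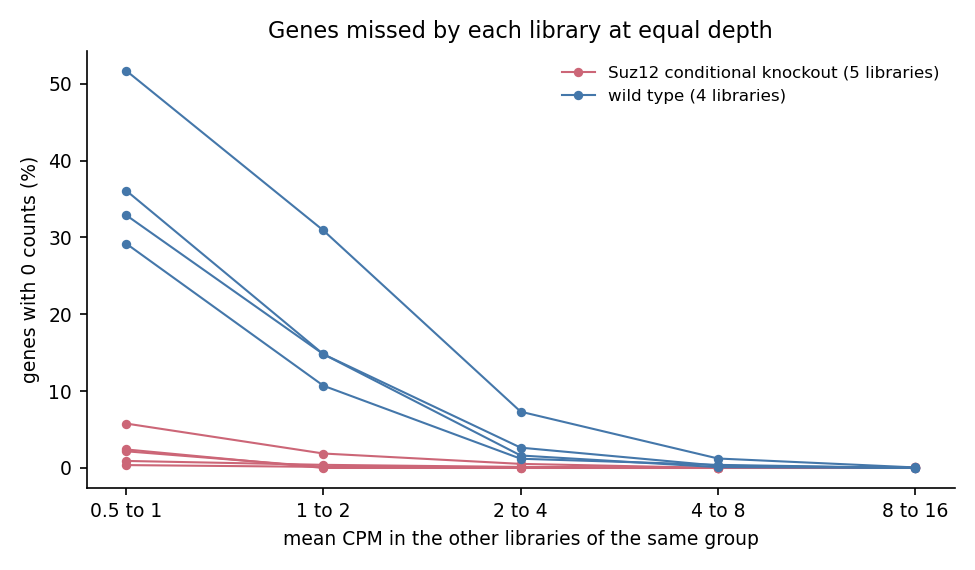
Percentage of genes with 0 counts in each library, with all libraries thinned to equal depth, by the mean CPM of the gene in the other libraries of the same group (x axis), for wild type (blue, 4 libraries) and knockout (red, 5 libraries). For genes at 1 to 2 CPM each wild type library lacked 10.7% to 30.9% and each knockout library at most 1.88%.

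Few PRC2 genes besides Suz12 changed. Of 13 tested components, Suz12 included, 1 was higher and 2 were lower, also when adjusted over the list alone. Rbbp4, a histone-binding subunit, fell from 365 ± 21.1 to 245 ± 16.5 CPM (log2 fold change -0.57), and Epop, an accessory subunit, rose from 2.96 ± 1.84 to 13 ± 1.49 CPM (2.14, SE 0.51). The catalytic subunit Ezh2 and the core subunit Eed, named after their values were seen, had log2 fold changes of 0.13 (SE 0.14, adjusted p = 0.567) and 0.21 (SE 0.10, adjusted p = 0.183) by edgeR. Of 20 PRC1 components 4 were higher and 1 lower, again also when adjusted over the list alone, with Bmi1 rising from 42.4 ± 6.85 to 79.6 ± 10.4 CPM (0.91, SE 0.13). Neither list was called by camera (adjusted p = 0.588 and 0.11), but PRC1 was called higher by fry (0.0161) and by camera among genes of mean log2 CPM of at least 4 (0.0477).

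Most classical Polycomb targets did not pass the count filter, which does not show that they were absent. Only 4 of 39 Hox genes and 11 of 128 developmental transcription factors passed the count filter. Hoxc4 was the single Hox gene called, with 0 counts in every wild type library and 0.809 ± 0.435 CPM in knockout (at least 22.4-fold higher). That bound covers counting error only. At 0.5 to 1 CPM in knockout 43 genes were absent from wild type, of which missed genes predict about 3.42, so loss in the wild type libraries is not excluded for Hoxc4. Of the developmental transcription factors 2 were higher and none lower, also when adjusted over the list alone. Zfp503 rose from 9.83 ± 2.95 to 19.2 ± 3.62 CPM (0.96, SE 0.21). Camera called this list higher (adjusted p = 0.026), but not with an estimated correlation (adjusted p = 0.237), without knockout library 3 (0.0591), with library size only (0.0769), with voom (0.0908), after the length correction (0.0861) or after correction for length and GC content (0.0997). Among 7 CDK inhibitors 2 were higher (2 adjusted over the list alone, camera adjusted p = 0.706). Cdkn2a, the locus of p16 and p19, rose from 0.376 ± 0.494 to 4.47 ± 2.68 CPM (log2 fold change 3.46, SE 0.87, adjusted p = 0.0126 by edgeR, and 0.0502 without knockout library 2). Without wild type library 2, which held the most Cdkn2a of its group (0.15 log2 CPM, the others -3.92 to -0.92), the log2 fold change was 4.64. Cdkn1a, which encodes p21, rose from 246 ± 26.3 to 371 ± 60.4 CPM (0.59).

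Immediate early and heat shock genes rose as a list. Of 32 tested, 12 were higher and 1 lower (14 and 2 adjusted over the list alone), with a median log2 fold change of 0.49, which was the same with genes absent from wild type set at their lower bounds. Atf3 rose from 84.8 ± 26.5 to 237 ± 20.2 CPM (1.49, SE 0.17), Fosl2 from 270 ± 58.5 to 566 ± 66.9 CPM (1.07, SE 0.13), and Egr3 from 0 counts in every wild type library to 3.63 ± 2.59 CPM (at least 101-fold higher). The member that fell, named after its values were seen, was the phosphatase Dusp1 (-1.03, SE 0.20). Camera called the list higher (adjusted p = 2.06e-04, and 2.43e-04 after the length correction), though not with an estimated correlation (adjusted p = 0.663).

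Transcripts of alveolar macrophage identity shifted in both directions and mostly downward. Of 41 tested, 16 were lower and 3 higher (17 and 4 adjusted over the list alone). The tetraspanin Cd9 fell from 5691 ± 580 to 3127 ± 218 CPM (-0.86, SE 0.08) and the cathepsin Ctsk from 822 ± 219 to 238 ± 53 CPM (-1.79, SE 0.19). The lipoprotein lipase Lpl rose from 1806 ± 186 to 2737 ± 101 CPM (0.60, SE 0.08), the scavenger receptor Marco from 563 ± 29.6 to 818 ± 50.9 CPM (0.54, SE 0.07), and the third riser, named after its values were seen, was Mgll (0.50). Camera called the list lower (adjusted p = 0.0012), but not with an estimated correlation (adjusted p = 0.237). After the length correction 10 members were lower and 7 higher (camera adjusted p = 0.0465), and after correction for length and GC content the adjusted p was 0.066.

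Some genes of DNA replication and mitosis fell. Of 55 S phase genes 8 were lower and of 53 G2 and mitosis genes 9 were lower, with none higher in either list and the same counts adjusted over the list alone. The replication clamp Pcna fell from 270 ± 25.3 to 177 ± 20.2 CPM (-0.61, SE 0.10), Orc6 of the origin recognition complex by 0.54 and Gins2 of the replicative helicase by 0.69 on the log2 scale. Cks2, a subunit of cyclin-dependent kinases, fell from 30.7 ± 5.78 to 15.0 ± 2.97 CPM (-1.03, SE 0.17), the mitotic kinase Cdk1 from 75.5 ± 8.84 to 46.7 ± 9.11 CPM (-0.69, SE 0.14) and the kinase Pbk by 0.85 on the log2 scale. Camera called both lists lower (adjusted p = 2.5e-04 and 0.0012), but neither was called with an estimated correlation (adjusted p = 0.768 and 0.785) or by fry (0.146 and 0.289). After the length correction the camera adjusted p was 3.16e-05 and 3.67e-05, while the called members dropped to 5 and 4. The medians went from -0.28 to -0.26 and from -0.23 to -0.21, and Gins2 and Orc6 were no longer called (adjusted p = 0.206 and 0.0533 by edgeR). The corrected log2 fold change of Cks2 was -0.51 and that of Pcna -0.35 (adjusted p = 0.0439 and 0.0249 by edgeR). For Cdk1 and for Pbk it was -0.70. Without knockout library 3 the adjusted p of the G2 and mitosis list was 0.102, and in the libraries with low Xist it was 0.101.

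Oxidative phosphorylation genes were lower as counted, together with short genes in general. Of 66 tested, 44 were lower and 1 higher (46 and 2 adjusted over the list alone), including the ATP synthase subunits Atp5e (-1.12, SE 0.12) and Atp5h (-0.82, SE 0.11) and the respiratory chain subunit Ndufa4 (-0.99, SE 0.13). Camera called the list lower (adjusted p = 4.53e-18), though not with an estimated correlation (adjusted p = 0.663). The median member was 680 bases long. After the length correction 9 members were higher and 8 lower, and the list's median log2 fold change went from -0.50 to 0.003. The call ended (camera adjusted p = 0.354). The corrected median of 0.003 stayed below that of all tested genes (0.08) and that of genes of 62 to 970 bases (0.125).

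**Figure D4:**
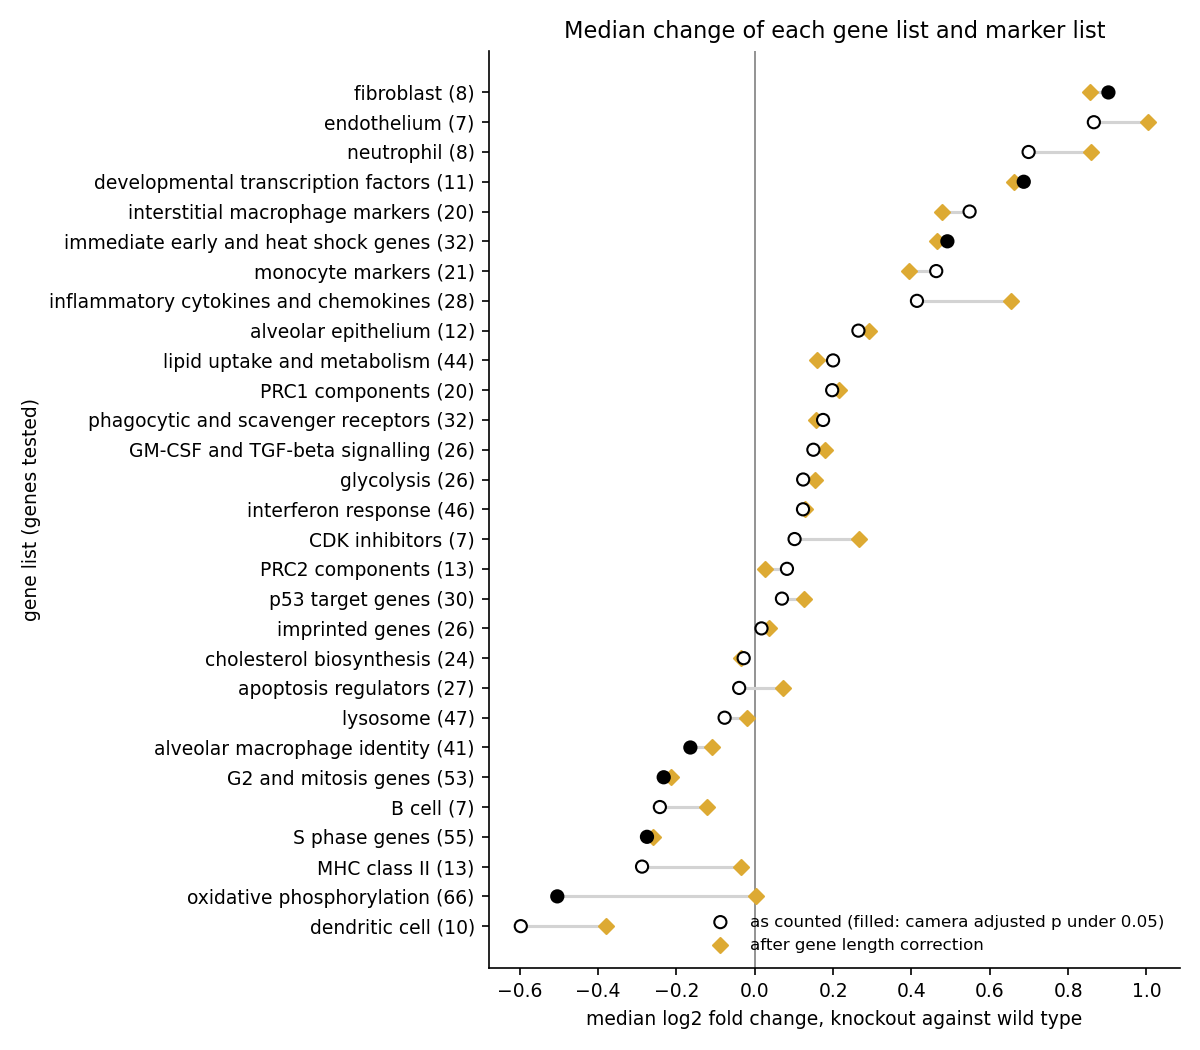
Median log2 fold change of knockout against wild type for each list with at least 5 tested genes, other than the sex-linked genes, as counted (circles, filled where the camera adjusted p was under 0.05) and after the length correction (diamonds). The oxidative phosphorylation list moves from -0.50 to 0.003 and the immediate early and heat shock list from 0.49 to 0.47. The median of all tested genes was 0.08 after the correction.

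Lipid, macrophage subset and immune lists held single genes with clear changes but were not called by camera as lists with all libraries and tested genes. Some nevertheless stood apart from random lists matched on length and expression, which ignore correlation between genes. Medians lay above their central range for cytokines (0.41, percentile 100), interstitial macrophage (0.55, 99.93) and monocyte markers (0.46, 99.98). So did those of the lipid (0.20, 99.98) and phagocytic receptor lists (0.17, 99.84). The interferon, MHC class II and lysosome lists lay within it (62.56, 15.62 and 2.51). Apoe, an apolipoprotein typical of interstitial macrophages, rose from 82.1 ± 17.6 to 750 ± 636 CPM (3.19, SE 0.61), and was among 2 genes higher of 20 interstitial macrophage markers (2 adjusted over the list alone, camera adjusted p = 0.428). Knockout library 3 had the most Apoe (10.87 log2 CPM, the others 8.38 to 9.20), and without it the log2 fold change was 2.53 (adjusted p = 9.71e-05 by edgeR). Of 44 lipid genes 9 were higher and 3 lower (11 and 4 adjusted over the list alone, camera adjusted p = 0.157, but 0.0161 by fry and 0.0496 among genes of mean log2 CPM of at least 4), with the cholesterol exporter Abca1 rising from 47.0 ± 8.41 to 102 ± 13.3 CPM (1.11). Of 21 monocyte markers 4 were higher and 2 lower (4 and 2 adjusted over the list alone, 0.428), among them the growth factor receptor Csf1r (0.47). Of 28 cytokine and chemokine genes 3 were higher and 4 lower (3 and 4 adjusted over the list alone, 0.943, but called higher without wild type library 3, 0.00493), and the chemokine Ccl6, among the most abundant transcripts, fell from 10330 ± 1613 to 4347 ± 215 CPM (-1.25, SE 0.10). Interferon response genes gave 4 higher and 3 lower of 46 (2 and 1 adjusted over the list alone, 0.428; Gbp5 1.30), and MHC class II genes gave 2 higher of 13 (2 adjusted over the list alone, 0.943; Cd86 0.80). Phagocytic and scavenger receptors gave 5 higher and 4 lower of 32 (6 and 4 adjusted over the list alone, 0.428), with Marco as above, and lysosome genes 2 higher and 4 lower of 47 (0 and 2 adjusted over the list alone, 0.367), with Ctsk as above.

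The remaining lists were not called by camera either, and with an estimated correlation no list of any kind had an adjusted p under 0.237. Of 30 p53 target genes 6 were higher and 1 lower (6 and 1 adjusted over the list alone, camera adjusted p = 0.367), led by the cell death gene Pmaip1, which rose from 18.6 ± 3.97 to 42.0 ± 4.51 CPM (1.18, SE 0.15). Of 27 apoptosis regulators 3 were higher and 4 lower (3 and 5 adjusted over the list alone, 0.588; Bcl2a1a -0.90). Of 26 glycolysis genes 5 were higher and 2 lower (7 and 2 adjusted over the list alone, 0.158), and the lactate dehydrogenase subunit Ldhb rose from 4.88 ± 2.89 to 19.8 ± 3.5 CPM (2.01, SE 0.30). Cholesterol biosynthesis gave 3 higher and 4 lower of 24 (3 and 6 adjusted over the list alone, 0.429; Msmo1 -0.75). GM-CSF and TGF-beta signalling gave 4 higher and 1 lower of 26 (4 and 1 adjusted over the list alone, 0.147; the repressor Skil 0.44). Imprinted genes gave 2 higher and 4 lower of 26 (2 and 4 adjusted over the list alone, 0.761; the tetraspanin Tspan32 -0.98). None of 5 sex-linked genes was called by edgeR, also when adjusted over the list alone (camera adjusted p = 0.706), and Xist was at 293 ± 200 CPM in wild type and 152 ± 208 CPM in knockout.

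Few markers of other lung cell types were called, among them some with large changes. Camera called the fibroblast list higher (adjusted p = 0.0254), but not with an estimated correlation (adjusted p = 0.237), without knockout library 1, 2 or 3 (0.0516, 0.062 and 0.0591), with the stricter filter (0.134), no filter (0.0557) or library size only (0.0524), after the length correction (0.0613) or that for length and GC content (0.0771), or in the libraries with low Xist (0.0859). Of its 8 tested genes 1 was called (2 adjusted over the list alone), Gsn (0.49), which was already at 241 CPM in wild type. Fn1 was at 1992 and 2795 CPM in wild type and knockout and was not called (adjusted p = 0.262 by edgeR), while the collagen genes Col1a1 and Col1a2 were under 2 CPM in both groups. The alveolar epithelium list gave 1 lower of 12, Hopx (-1.28), and endothelium 1 higher and 1 lower of 7, Esam (3.58) and Calcrl (-0.85). Neutrophil genes gave 1 higher of 8, Csf3r (20.9 to 49.9 CPM), dendritic cell genes 1 lower of 10, Ccr7 (-2.09), and B cell genes 0 of 7. Adjusted over the list alone, the called genes numbered 1 lower, 3 higher and 2 lower, 1 higher, 0 and 0 in these 5 lists, and none of the 5 was called by camera (adjusted p = 0.943, 0.719, 0.618, 0.588 and 0.673). Against random lists matched on length and expression, the neutrophil median lay above the central range (percentile 99.71) and the dendritic cell median below it (0.43). The alveolar epithelium, endothelium and B cell medians lay within it (84.44, 92.8 and 11.59). In the libraries with low Xist, which include a single wild type library, camera gave endothelium as higher and B cell, airway epithelium and T and NK cell genes as lower. These shifts cannot be told apart from the content of wild type library 4, because no spread within wild type can be estimated there. The marker genes above were named after their values were seen. Of 4 T and NK cell genes 1 was lower, Il7r (-1.36), and none was called among 3 airway epithelium, 1 eosinophil, 4 erythroid and 3 platelet genes, with the same counts adjusted over the list alone. No mast cell or basophil gene passed the filter. The surfactant gene Sftpc was at 7.01 ± 3.79 CPM in wild type (n = 4) and 4.74 ± 1.44 CPM in knockout (n = 5; exact permutation p = 0.294).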

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

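The tests of library complexity and of dissociation genes were chosen only after the results they bear on had been seen, as was the length correction. Groups of libraries were compared with random splits of the same 9 libraries. For the counts of genes, no other of 100 splits gave as many: the highest other split gave 696 genes in either direction against 1152 higher and 1409 lower, and only 1 of 100 splits, the real one, was as large for each count. The 2 highest other splits, with 696 and 547 genes, set 4 knockout libraries against the remaining knockout library and all wild type libraries, and the other 2 drawn splits of that composition gave 0 genes in either direction. For the counts of lists chance cannot be excluded, since 81 of the 100 splits gave at least 3 lists in some direction and 65 gave at least 4, with 11 as the highest other value for both, against the real 3 higher and 4 lower.

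For the decrease of oxidative phosphorylation genes, gene length bias between the libraries remains a candidate explanation, because the list's median log2 fold change of -0.50 lay at percentile 21 of random lists matched on length and expression, whose central range ran from -0.57 to -0.33. The medians of the alveolar macrophage identity, developmental transcription factor and fibroblast lists also lay within the central range of such lists, at percentiles 8.41, 78.5 and 94.1, while those of the S phase and the G2 and mitosis lists lay outside it, at percentile 0. Per library, wild type library 2, with the flattest length slope of its group (0.011 log2 units per doubling), also had the lowest mean of oxidative phosphorylation genes in wild type (6.67 log2 CPM, against 6.94 to 7.15). Members above a mean log2 CPM of 6 still had a median of -0.48, so the fall was not confined to members near the detection floor. Genes missed in wild type would make members higher in knockout, but of 66 members 44 were lower and 1 higher. For these members the values argue against missed genes as the source of the fall. Whether lower complexity of the wild type libraries acted in another way was not tested. An effect of the loss of Suz12 cannot be told apart from none, as library quality followed genotype in this design. The list's median after the length correction was 0.00311, against 0.08 for all tested genes and 0.125 for genes of 62 to 970 bases. Its 95% range, -0.07 to 0.08, was taken over the 66 member genes as if they were independent. That range does not measure variation between libraries and sets no limit on an effect of the knockout.

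Some genes were at 0 counts in all 4 wild type libraries and present in knockout. At equal depth each wild type library missed 10.7% to 30.9% of genes that stood at 1 to 2 CPM in the rest of its group, and each knockout library at most 1.88%, so lower complexity of the wild type libraries was weighed as a technical explanation. At 2 CPM or more in knockout there were 7 such genes, where each wild type library's own rate of missed genes predicts 0.00053 with an upper limit of 0. For these 7 this argues against loss that is independent in each wild type library. The rate came from genes that another wild type library detected, so it does not cover loss shared by all 4. No tested gene was absent from every knockout library, a one-sided pattern that lower complexity of wild type would also give. The 7 genes included Iqcn, Egr3, Igf2bp1, Ndnf, Zfp651 and Maged2, all but Egr3 named after their values were seen. That they are silenced by PRC2 in wild type macrophages may be proposed as a hypothesis, which was not tested because no histone data were used here, and of the 43 such genes at 0.5 to 1 CPM about 3.42 are predicted by missed genes.

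The increase of immediate early and heat shock genes could reflect biology or handling. Gene length bias is argued against, since the list's median lay at percentile 100 of matched random lists. More cell stress during dissociation and sorting cannot be told apart from an effect of Suz12 loss, because of 9 canonical dissociation genes 1 was higher (Junb, 0.78, adjusted p = 0.0477 by edgeR) and 1 lower (Dusp1, -1.03, adjusted p = 0.005), with a median log2 fold change of 0.182. Fos was at 1739 CPM in wild type and 1726 CPM in knockout, and the 9 genes were picked after the results were seen, leaving out members that rose, such as Atf3, Fosl2 and Egr3. The genotype is the biological explanation the design gives, and it stays untested beyond these comparisons.

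In 8 of 117 groups of libraries the highest or lowest library stood apart from the rest of its group by Dixon's test, where chance gives about 5.85, and each is given by the ratio of its gap to the group's range. Lpl was higher in wild type library 2 (11.02 log2 CPM, the others 10.72 to 10.75, ratio 0.883). Msmo1 was lower in knockout library 1 (6.44, the others 6.78 to 6.89, ratio 0.752). Ldhb was higher in wild type library 1 (3.22, the others 1.77 to 1.86, ratio 0.936). Id3 was lower in wild type library 2 (3.12, the others 3.53 to 3.60, ratio 0.852). Lars2 was lower in knockout library 5 (7.98, the others 9.18 to 9.65, ratio 0.717). Egln3 was lower in wild type library 3 (-3.92, the others 0.36 to 0.70, ratio 0.927). Epop was lower in wild type library 4 (-1.65, the others 1.80 to 2.11, ratio 0.918). Xist was lower in wild type library 4 (-3.21, the others 8.39 to 8.81, ratio 0.965).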

How the results depend on the processing

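The corrections for length and GC content, the restriction to abundant genes, the thinned libraries and the splits by Xist level were chosen after seeing the data. The Suz12 log2 fold change kept its direction and its side of the threshold under all 25 alternatives, between -2.19 and -1.95. Genes higher in knockout numbered 1152, but 1753 with DESeq2, 1966 with library size only, 129 against a 1.5-fold minimum change, 199 in the libraries with high Xist and 472 in those with low Xist. Genes lower numbered 1409, but 835 with the length correction, 862 with length and GC correction, 95 against the 1.5-fold minimum, 646 with high Xist and 520 with low Xist. The splits by Xist hold fewer samples (5 and 4 libraries, the latter with a single wild type library, assumed to vary like the knockout libraries), and the 1.5-fold test asks for more by construction. For the other changes the cause was not tested, apart from the length trend that the length correction removes. Without each library in turn, 772 to 1434 genes were higher and 1074 to 1521 lower. Lists higher numbered 3, but 0 with an estimated correlation, 9 with fry, and 1 each with library size only, length correction, and length and GC correction. Fry alone of the 3 list tests called PRC1, lipid, interferon response, phagocytic receptors, glycolysis and GM-CSF and TGF-beta signalling, of which PRC1 and lipid were also called among abundant genes and GM-CSF and TGF-beta signalling in the libraries with high Xist. Lists lower numbered 4, but 0 with an estimated correlation, 2 with fry, 2 with length and GC correction, 5 in the libraries with high Xist (lysosome added) and 6 in those with low Xist (airway epithelium, T and NK cell and B cell added, G2 and mitosis lost). Without each library the counts of lists were 1 to 4 higher and 3 to 4 lower, and the 1 came without knockout library 3. With the replicate block, 749 genes were higher and 1103 lower, and the lists stayed at 3 and 4. Correlations of same-numbered libraries across genes were 0.0344, 0.0578, -0.105 and 0.156, and only wild type library 4 correlated best with its own number. They show no pairing by the numbers in the titles. They cannot exclude one, because differences of Xist level and length trend within each group also enter them. Counts from the single tables were not run as an alternative because their values were identical. Of 1302 values of the other 53 named genes under alternatives, none reversed, 1201 kept direction and side of the threshold and 101 fell short of it, with 27 of these in the low-Xist libraries, 25 against the 1.5-fold minimum and 12 in the high-Xist libraries. The replicate block ended 9 calls, and voom with quality weights ended 7, including Plcb4 (adjusted p = 0.223). With the length correction 9 of the genes called without it were called in the opposite direction.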

Other observations

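The region, orphan receptor and cytokine comparisons here were chosen after seeing the data. Several of the strongest decreases were neighbours. Ccl9 (-2.28), Ccl6 (-1.25), Wfdc17 (-2.17) and Wfdc21 (-2.50) lie within 180 kilobases of chromosome 11, from 83572917 to 83752646 of GRCm38, and of the 7 tested genes in that span 5 were lower and 0 higher. The span was set to run from Ccl9 to Wfdc21, so both its ends are called genes by construction and the count is no test of the region. After the length correction the 4 values were -2.30, -1.04, -1.52 and -1.84. The fifth was the noncoding E230016K23Rik (-1.11, adjusted p = 0.0440 by edgeR), which overlaps Ccl6, and the chemokines Ccl3 (-0.30, adjusted p = 0.648) and Ccl4 (0.13, adjusted p = 0.901) were not called. The span begins 3.54 megabases from Suz12. Within 5 megabases of Suz12, 25 of 130 tested genes were called (19.2%), against 20% of 12383 genes elsewhere (two-sided Fisher's exact p = 0.912, over genes, which are not independent), so called genes as a whole were not concentrated near the targeted locus.

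The NR4A orphan nuclear receptors rose together: Nr4a1 from 152 to 678 CPM (log2 fold change 2.16, SE 0.37), Nr4a2 from 12.0 to 69.8 CPM (2.57, SE 0.54) and Nr4a3 from 3.95 to 35.4 CPM (3.30, SE 0.84), with adjusted p of 0.00479, 0.0125 and 0.0289 by edgeR. The wild type mean of Nr4a3 rests on library 3 (3.59 log2 CPM, the others -0.41 to 1.02), and without it the log2 fold change was 4.80. Among cytokines the directions were mixed: Il1b rose from 51.3 to 203 CPM (2, SE 0.48) and Cxcl14 from 4.83 to 18.2 CPM (1.91, SE 0.22), while Il18 (-0.78, SE 0.13) and the interleukin 1 receptor antagonist Il1rn (-0.62, SE 0.09) fell. The PRC1 genes Rnf2 (0.65) and Rybp (0.70) rose beside Bmi1, and Yaf2 (-0.46) fell.

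The sex of the mice is not in the labels. Xist was above 336 CPM in wild type libraries 1, 2 and 3 and knockout libraries 2 and 5, where the Y-linked Ddx3y was under 0.25 CPM. In wild type library 4 and knockout libraries 1, 3 and 4, Xist was under 0.14 CPM and Ddx3y between 69.9 and 81.2 CPM. A single identifier without a symbol took 2.03 ± 0.58% of counts in wild type (n = 4) and 0.230 ± 0.079% in knockout (n = 5; exact permutation p = 0.00794). Both it and Lars2 were lowest in knockout library 5 (0.150%, 7.98 log2 CPM) and highest in library 4 (0.339%, 9.65). In wild type both were lowest in library 2 (1.54%, 11.42) and highest in library 3 (2.86%, 11.73). Libraries in between differed in order, and Malat1 did not follow. Whether the fall of Lars2 reflects library composition was not tested.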
